A study of Homo sapiens with 6 samples.

How the data were processed

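The series holds RNA sequencing of CT27 human trophoblast stem cells, an established line, kept for 8 days in medium that drives extravillous trophoblast (EVT) differentiation. Cells received vehicle or 2 µM CHIR99021, an inhibitor of the kinase GSK3, with 3 libraries in each group. The labels state 3 experiments per group. They do not say that equal replicate numbers mark a shared experiment, so the libraries were treated as unpaired. Groups were taken from the sample titles.

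Libraries were made from total RNA with TruSeq kits and sequenced as paired-end reads, per the labels' protocols. The labels disagree on part of the upstream work. Reads were mapped to GRCh37 with CLC Genomics Workbench 12.0, per the labels' descriptions. The labels' extraction protocol names a rat assembly, another sequencer model and a comparison of glucose levels, none of which match the human gene symbols of the deposited table. GRCh37 was therefore taken as the build. The transcript annotation is not given in the sources used here.

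The deposited values are RPKM, reads per kilobase of exon scaled to the mapped reads of the library, with 1 value per transcript and library, per the file headers. The table also holds the p-value and the FDR-corrected p-value of an EDGE test with tagwise dispersions between vehicle and CHIR99021, per the file headers. Its fold change column is a signed score that is positive where CHIR99021 was higher and minus the inverse ratio where it was lower, per the file headers and the signs of the values. The table listed 173113 transcripts of 36479 gene symbols, of which 11848 symbols were at 0 in all 6 libraries.

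RPKM of the transcripts of each symbol were summed per library. The plan, set before the data were examined, was a test on read counts, with limma on log2(RPKM + 1) as the stated alternative for a table without counts. The table holds no counts, so that alternative was used. Genes with a mean of at least 1 RPKM in either group were kept, which left 12396 genes. A linear model with group as its only term was fitted with limma 3.58.1 in R 4.3.3, with the trend option of its empirical Bayes step. Two-sided p-values were adjusted by Benjamini-Hochberg over all genes tested, and genes with an adjusted p under 0.05 were called. Fold changes are CHIR99021 over vehicle on the log2(RPKM + 1) scale, which understates the change of genes with few RPKM. Folds of means are ratios of mean RPKM.

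Gene lists were fixed before the data were examined. They covered WNT targets, WNT ligands and receptors, the beta-catenin destruction complex with its TCF/LEF partners, EVT markers, stem and cytotrophoblast markers, proximal column markers, and syncytiotrophoblast markers. Further lists covered DNA replication, mitosis, matrix proteases, TGF-beta response, YAP/TEAD targets, hypoxia and glycolysis, the unfolded protein and ATF4 response, and interferon response. The remaining lists covered cholesterol synthesis, primitive streak, amnion, fibroblast and stroma, endothelial and blood markers, and mitochondrial transcripts. Of the 21 lists, 20 had at least 3 tested members. These 20 were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 20 lists. Each was also tested with the correlation estimated per list, and with fry, which asks whether a list moves one way but does not compare it with other genes. Members were matched by current or older symbol. Some genes belong to several lists, so the lists are not independent of each other.

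The rule for naming genes was also set before the data were examined. It names 12 fixed genes (NOTUM, AXIN2, LEF1, GSK3A, GSK3B, CTNNB1, HLA-G, MMP2, ITGA1, ASCL2, TEAD4 and CGA). It adds the 5 called genes with the largest rise and the 5 with the largest fall among those with at least 5 TPM in the higher group and no overlap between groups. It further adds the 2 members with the smallest p from each of 9 main lists, and the member with the smallest p from each other list where that member was called. Other list members and family members printed in the text were chosen after their values were seen. Sex-linked genes were left out of the naming, and so were clone names without a gene symbol. Positions are those of GENCODE 44 lifted to GRCh37.

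Depth per library was recovered from the RPKM themselves. In genes with 1 transcript, an RPKM times the transcript length in kilobases is a whole read count divided by a scaled total. The most frequent product among these genes in a library was taken to stand for 1 read, which gave the total. Between 40.1% and 42.8% of such genes above 0 in a library lay within 0.02 of a whole number. Whether CLC counted reads or read pairs is unknown. The recovered totals ran from 18314452 to 30510739, so that 1 RPKM on a transcript of 1 kb stood for 18.3 to 30.5 reads. Counting noise was compared with the differences between libraries by a chi-square test over 100 genes with at least 5 reads.

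The steps were tested on simulated data with 12396 genes, of which 200 were changed. For CHIR99021 against vehicle, limma called 55.2% of the genes changed 1.5-fold, 74.6% of those changed 2-fold and 97.0% of those changed 4-fold, all in the right direction, and 4 unchanged genes. Changed genes were drawn from those with a vehicle mean above 2 on the log2(RPKM + 1) scale, although lower genes were tested in the data. Noise was normal with a single SD per gene and no outlying library, and far fewer genes were changed than were called in the data. The shares therefore check the steps and do not estimate power in these data.

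Alternatives set before the data were examined were no filter on low values, a filter of at least 5 RPKM in 3 libraries, a pseudocount of 0.1, a replicate block, leaving out each library, a fold minimum of 2, an estimated correlation, and fry. Alternatives chosen after seeing the data were TPM (each library's RPKM divided by their sum, with values above the RPKM, so that the same filter and pseudocount of 1 are in effect lower), median-of-ratios scaling, values rescaled without mitochondrial transcripts, leaving out vehicle replicate 3 with CHIR99021 replicate 1, and a fit of transcripts in place of genes. Count-based fits and a comparison of unique with total reads were left out, because the table holds neither counts nor both kinds of read. Principal components were computed from the 1000 most variable genes. All 10 splits of the 6 libraries into groups of 3 were fitted in the same way. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.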

Results

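RNA was sequenced from CT27 human trophoblast stem cells after 8 days in conditions that drive differentiation into extravillous trophoblast (EVT), the invasive cell type of the placenta. Cells were exposed to vehicle (3 libraries) or to 2 µM CHIR99021 (3 libraries), a small molecule that blocks GSK3 and so activates canonical WNT signalling. Totals recovered from the values were 29971309, 18314452 and 30510739 reads for vehicle replicates 1, 2 and 3. They were 29599909, 25787867 and 29793676 reads for CHIR99021 replicates 1, 2 and 3. Between 19426 and 20729 gene symbols lay above 0 in a library, and 12396 genes had enough signal to be tested.

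Libraries grouped by treatment. Across the 12396 genes, which are not independent replicates, Pearson r of log2(RPKM + 1) was 0.993 to 0.996 between vehicle libraries and 0.902 to 0.921 between groups. CHIR99021 replicates 2 and 3 had an r of 0.997, whereas replicate 1 had 0.973 with each of them. The first principal component held 90.9% of the variance of the 1000 most variable genes and separated the treatments, and the second held 7.47% and set CHIR99021 replicate 1 apart. No pair of libraries was alike within counting noise. The closest pair, CHIR99021 replicates 2 and 3, differed by a chi-square of 2.61 per degree of freedom over 100 genes. This value was 6.84 to 19.7 between vehicle libraries, and 41.0 and 46.0 for CHIR99021 replicate 1 against replicates 2 and 3. Why replicates 2 and 3 were so much closer than other pairs was not tested.

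**Figure D1:**
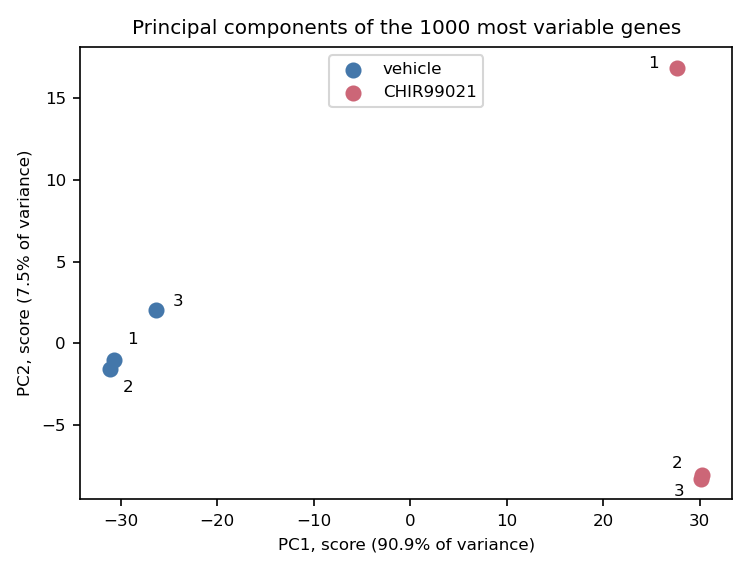
Principal components 1 and 2 of the 1000 most variable genes on the log2(RPKM + 1) scale, with 1 point per library and its replicate number beside it. The vehicle libraries lie between -31.1 and -26.3 on component 1 and the CHIR99021 libraries between 27.7 and 30.3, while CHIR99021 replicate 1 lies at 16.9 on component 2 against -8.27 and -8.08 for the other two.

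The comparison asks how activation of WNT signalling during EVT differentiation alters the transcriptome of the differentiating cells. All 6 libraries are of day 8. Rises and falls are therefore differences from vehicle at that day, and change over time was not measured. HLA-G, the class I molecule that EVT cells present to maternal immune cells, fell from 680 ± 58.0 RPKM (SD, n = 3) with vehicle to 31.1 ± 7.59 (SD, n = 3) with CHIR99021. The matrix protease MMP2 fell from 704 ± 39.8 to 25 ± 4.29 RPKM. NOTUM, a secreted enzyme that inactivates WNT ligands, fell from 613 ± 183 to 17.3 ± 14.5 RPKM. TEAD4, a transcription factor of trophoblast stem cells, rose from 7.56 ± 0.929 to 47.9 ± 4.19 RPKM, and the proliferation marker MKI67 rose from 6.65 ± 0.685 to 27.4 ± 1.04 RPKM. For each of these 5 genes every CHIR99021 library lay outside the range of the vehicle libraries. The adjusted p (limma, Benjamini-Hochberg) was 6.99e-06 for HLA-G, 3.02e-06 for MMP2, 0.000178 for NOTUM, 9.77e-06 for TEAD4 and 1.22e-05 for MKI67.

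Across the transcriptome limma called 7477 genes, 60.3% of those tested, with 4898 higher and 2579 lower with CHIR99021. At an unadjusted p under 0.05 the count was 8062. The groups did not overlap in 8524 genes (68.8%), where chance gives 10%. The median gene had a log2 fold change of 0.18, which median-of-ratios scaling of the same 12396 genes shifted by -0.17. The split between higher and lower depended on that shift, with 3361 higher and 3549 lower under median-of-ratios scaling. TPM, on which the filter and pseudocount of 1 are in effect lower, tested 13911 genes with a median of 0.055 (-0.12 from 0.18), and called 3967 higher and 3437 lower. Called genes with at least a 2-fold change numbered 707 higher and 781 lower on the log2(RPKM + 1) scale, and 1143 higher and 1078 lower by the ratio of mean RPKM. With at least an 8-fold change they numbered 1 higher and 51 lower on that log scale, which compresses changes of low genes, and 13 higher and 169 lower by the ratio of means.

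**Figure D2:**
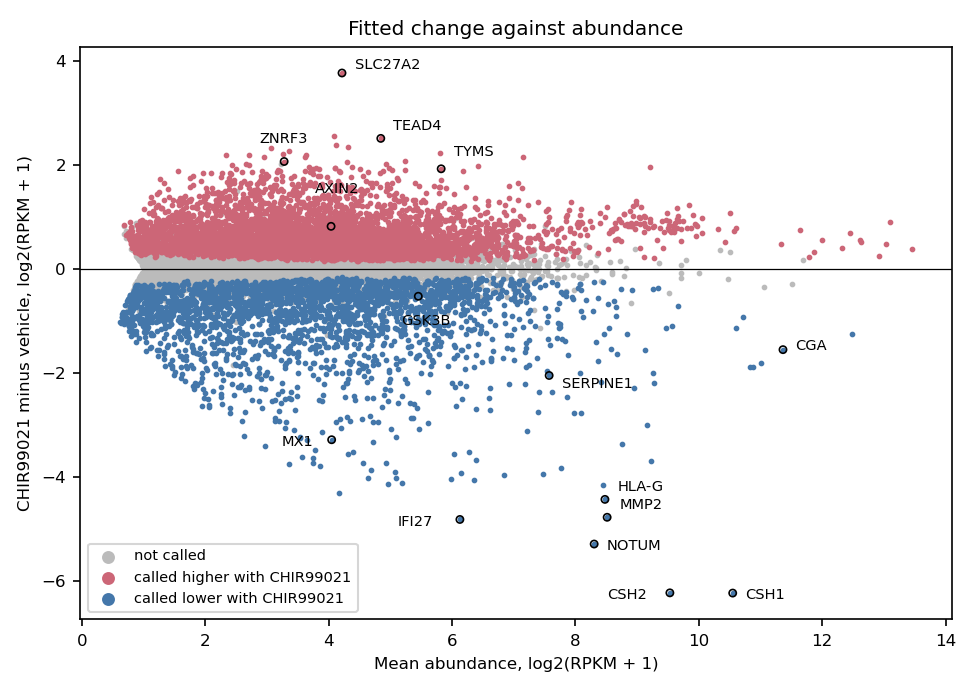
Log2 fold change (CHIR99021 over vehicle, log2(RPKM + 1) scale) of each of the 12396 tested genes against its mean abundance, with called genes in red (4898 higher) or blue (2579 lower) and others in grey. Among the labelled genes, CSH1 lies at -6.23, NOTUM at -5.29, MMP2 at -4.77 and TEAD4 at 2.52.

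Among the largest rises on the log2(RPKM + 1) scale was SLC27A2, a fatty acid transporter and acyl-CoA synthetase (chromosome 15, 50474393 to 50528582 in GRCh37). It rose from 1.19 ± 0.143 to 34 ± 19.5 RPKM (log2 fold change 3.77, or 4.40 without CHIR99021 replicate 1; adjusted p in limma 0.000645). NRP1, a co-receptor for semaphorins and VEGF, rose from 4.51 ± 0.214 to 33.2 ± 20.9 RPKM, with a log2 fold change of 2.34 that became 3.07 without CHIR99021 replicate 1. KIAA0101 (PCLAF), a PCNA-binding factor, rose from 3.93 ± 0.902 to 27.9 ± 0.910 RPKM. BMP7, a secreted growth factor, rose from 4.33 ± 0.790 to 28.5 ± 13.3 RPKM. The placental lactogen genes CSH1 and CSH2 were among the largest falls on that scale. CSH1 fell from 2938 ± 354 to 58.6 ± 67.2 RPKM (log2 fold change -6.23, or -7.14 without CHIR99021 replicate 1). CSH2 fell from 1449 ± 177 to 28.4 ± 33.1 RPKM (-6.22, or -7.13 without that library). Reads of these paralogs can be assigned to either gene, so their separate values are uncertain. IFI27, an interferon response gene, was 33.8-fold lower, at 3.96 ± 1.70 RPKM against 134 ± 9.30.

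EVT markers fell almost as a whole. Of 34 tested members of the list, 32 were lower, 0 higher and 2 not called, and adjusted over the list alone 32 were lower. The list's median log2 fold change was -2.86 and camera gave an adjusted p of 4.99e-21, with an adjusted p = 0.0727 with an estimated correlation. MMP2 (chromosome 16, 55423612 to 55540603) was 28.2-fold lower and HLA-G (chromosome 6, 29794744 to 29798902) 21.8-fold lower, although reads of HLA paralogs are hard to tell apart. NOTUM (chromosome 17, 79910383 to 79919716) was 35.3-fold lower (68.0-fold without CHIR99021 replicate 1), with a log2 fold change of -5.29 that became -5.89 without that library. ITGA1, the collagen-binding integrin of mature EVT, fell from 69.6 ± 5.11 to 12.3 ± 6.88 RPKM (adjusted p in limma 0.00215). ASCL2, a transcription factor that drives EVT differentiation, fell from 73.0 ± 5.25 to 10.9 ± 2.83 RPKM. DIO2, a deiodinase that activates thyroid hormone, fell from 154 ± 2.97 to 11.3 ± 1.51 RPKM. Further members, chosen after their values were seen, included the protease HTRA4, which fell from 663 ± 56.3 to 36.3 ± 5.81 RPKM, and the activin antagonist FSTL3, which fell from 1104 ± 73.1 to 84.6 ± 9.98 RPKM. The members not called were KRT7, at 180.1 ± 0.975 against 227 ± 71.5 RPKM, and LPCAT1, at 21.1 ± 0.781 against 19.2 ± 6.90 RPKM. PAPPA2 was too low to test.

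Matrix genes followed. Of 28 tested matrix proteases, inhibitors and basement membrane genes, 21 were lower, 0 higher and 7 not called, with 22 lower adjusted over the list alone, and 2 higher and 25 lower without CHIR99021 replicate 1 (camera adjusted p 4.49e-14, and adjusted p = 0.0603 with an estimated correlation). Members chosen after their values were seen included the basement membrane collagen COL4A1, which fell from 474 ± 20.2 to 68.9 ± 6.93 RPKM, and SPARC, a matrix-binding protein, which fell from 786 ± 84.3 to 76.4 ± 19.5 RPKM. In the TGF-beta response list, 12 of 18 tested members were lower, 1 higher and 5 not called, with the same counts of 12 and 1 adjusted over the list alone (camera adjusted p 3.4e-05, and adjusted p = 0.0603 with an estimated correlation). SERPINE1, an inhibitor of plasminogen activators, fell from 306 ± 0.889 to 73.4 ± 2.74 RPKM. TGFB1 and SNAI1, also chosen after their values were seen, had log2 fold changes of -1.71 and -2.47. The only member called higher was SKI, at 0.23, a call that was lost under TPM, under median-of-ratios scaling, and without any 1 library other than CHIR99021 replicate 1. Without CHIR99021 replicate 1, ID2 was called higher too.

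WNT pathway genes moved in both directions. AXIN2 (chromosome 17, 63524681 to 63557766), a scaffold of the destruction complex and target of beta-catenin, rose from 10.9 ± 0.963 to 19.99 ± 1.28 RPKM (log2 fold change 0.82, adjusted p in limma 0.000262). ZNRF3, a ubiquitin ligase that removes WNT receptors, rose from 2.73 ± 0.155 to 14.7 ± 0.643 RPKM. Its relative RNF43, chosen after its values were seen like TCF7, MYC, CCND1 and TNFRSF19, rose from 2.58 ± 0.437 to 7.68 ± 0.770 RPKM. TCF7, a nuclear partner of beta-catenin, rose from 0.576 ± 0.181 to 5.18 ± 3.23 RPKM, or to a mean of 3.32 RPKM without CHIR99021 replicate 1 (log2 fold change 1.86, or 1.46 without it). MYC rose from 7.41 ± 0.869 to 14.2 ± 4.88 RPKM, with an adjusted p in limma of 0.0139 that was 0.0535 without vehicle replicate 1. Of 25 fixed members of the target list 11 were tested, and the rest had means under 1 RPKM in both groups. The tested members were 5 higher, 2 lower (NOTUM and ASCL2) and 4 not called, with 5 higher and 2 lower adjusted over the list alone. The list's median log2 fold change was 0.82 (0.46, with 7 higher and 2 lower, without CHIR99021 replicate 1) and its mean 0.11. Camera did not separate the list from other genes (adjusted p 0.567). CCND1 was at 8.45 ± 1.52 against 21.5 ± 16.6 RPKM and was not called, as was TNFRSF19. Both were called higher without CHIR99021 replicate 1, with log2 fold changes of 0.46 and 0.36. TNFRSF19 had a mean of 0.165 RPKM with vehicle and, without that library, 0.490 RPKM with CHIR99021. It passed the filter only through CHIR99021 replicate 1, and the 7 higher members include it. LEF1, a TCF/LEF factor, was too low to test, at 0.152 ± 0.124 against 0.190 ± 0.245 RPKM.

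Among WNT ligands and receptors, ROR2, a WNT5A receptor, rose from 0.804 ± 0.139 to 7.26 ± 0.803 RPKM. The ligand WNT7A fell from 29.5 ± 0.430 to 7.85 ± 0.921 RPKM. Of 19 tested members, 8 were higher, 5 lower and 6 not called, with 8 and 5 adjusted over the list alone (camera adjusted p 0.902, median log2 fold change 0.37). Under median-of-ratios scaling 6 were higher and 6 lower. In the destruction complex list, TCF7L1, a repressor of WNT targets, fell from 20.1 ± 0.906 to 5.07 ± 0.236 RPKM, and the scaffold AXIN1 fell from 26.8 ± 0.947 to 13.6 ± 1.47 RPKM. GSK3B, a target of the inhibitor, fell from 50.6 ± 1.85 to 35 ± 0.581 RPKM (adjusted p in limma 0.000319). GSK3A, its other isoform, was not called at 31.1 ± 0.699 against 35.9 ± 3.98 RPKM (adjusted p in limma 0.0848). CTNNB1, which encodes beta-catenin, was at 122 ± 5.94 against 129 ± 18.8 RPKM and was not called (log2 fold change 0.08, adjusted p in limma 0.581). Its change took the opposite sign under TPM (-0.053) and median-of-ratios scaling (-0.12), and without CHIR99021 replicate 1 it was called higher (0.20, adjusted p in limma 0.00589). That list held 4 higher, 5 lower and 10 not called members among 19 tested, with 4 and 5 adjusted over the list alone. Its median was -0.01, its mean -0.15, and camera's adjusted p 0.147. Counts became 2 higher and 9 lower under median-of-ratios scaling, and 6 and 6, with a median of 0.11, without CHIR99021 replicate 1.

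Several stem cell genes rose, while camera did not separate their list from other genes. Those called higher made up 34.5% of the list, where 4898 of all 12396 tested genes were called higher. TEAD4 (chromosome 12, 3068496 to 3149842) was 6.33-fold and MKI67, which is also in the mitosis list, 4.11-fold higher. Members chosen after their values were seen included EPCAM, an adhesion molecule of cytotrophoblast, which rose from 30.05 ± 3.74 to 113 ± 5.89 RPKM. The endocytic receptor LRP2 rose from 18.7 ± 3.37 to 91.5 ± 8.01 RPKM, and the TEAD partner YAP1 from 38.7 ± 2.94 to 89.5 ± 6.30 RPKM. EGFR, GATA2, TFAP2A and GATA3 were the 4 lower members, with log2 fold changes of -0.61, -0.52, -0.46 and -0.29. TP63 (-0.16) was not called. ITGA6 was at 77.9 ± 2.56 against 77.2 ± 2.49 RPKM and was called, as lower, only under median-of-ratios scaling. Of 29 tested stem and cytotrophoblast markers, 10 were higher, 4 lower and 15 not called, with 9 and 4 adjusted over the list alone (median 0.35, camera adjusted p 0.567). Without CHIR99021 replicate 1 the counts were 16 and 7, and under median-of-ratios scaling 9 and 8. Proximal column markers, of EVT progenitors, had 4 tested members with 2 higher, 1 lower and 1 not called, and 2 and 1 adjusted over the list alone (camera adjusted p 0.828). NOTCH1, a receptor of column progenitors, rose from 3.17 ± 0.260 to 6.17 ± 1.49 RPKM. SOX15, a transcription factor, rose from 7.91 ± 2.02 to 21.9 ± 13.3 RPKM, or to a mean of 14.3 RPKM without CHIR99021 replicate 1 (adjusted p in limma 0.0236, but 0.0787 without vehicle replicate 1 and 0.0811 without vehicle replicate 2). Without vehicle replicate 1 or 2, SOX15 lost its call and left 1 higher member. ITGB6, the lower member, kept its call only when CHIR99021 replicate 1 was the library left out.

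Syncytiotrophoblast markers, of the hormone-secreting layer, fell too. HSD3B1, an enzyme of progesterone synthesis, fell from 329 ± 2.97 to 63.6 ± 2.46 RPKM (log2 fold change -2.35, adjusted p in limma 3.02e-06). GH2, placental growth hormone, fell from 5.66 ± 1.26 to 0.177 ± 0.117 RPKM, or to a mean of 0.112 RPKM without CHIR99021 replicate 1. CGA, the alpha subunit of chorionic gonadotropin, fell from 3803 ± 868 to 1469.8 ± 788 RPKM (log2 fold change -1.55, adjusted p in limma 0.0280). Its adjusted p was 0.0841 without vehicle replicate 1 and 0.0933 without vehicle replicate 2, and its log2 fold change was -0.95 without CHIR99021 replicate 1. GCM1, chosen after its values were seen, drives trophoblast fusion and fell from 102 ± 1.97 to 23.4 ± 10.1 RPKM. Of 38 tested members, 34 were lower, 0 higher and 4 not called, with 37 lower adjusted over the list alone. Camera gave an adjusted p of 6.67e-14 for a median log2 fold change of -1.69, with an adjusted p = 0.0905 with an estimated correlation. The members not called were CGB2, ERVW-1, HSD17B1 and CYP19A1, the last at 226 ± 31.6 against 115 ± 57.5 RPKM (adjusted p in limma 0.0514). All 4 had a lower mean with CHIR99021 and were called lower without CHIR99021 replicate 1 or under median-of-ratios scaling. Values of single CGB, CSH and PSG genes are uncertain, since their sequences are alike.

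Proliferation genes rose as a group. TYMS, which makes thymidylate for DNA synthesis, rose from 22.6 ± 1.59 to 88.7 ± 0.316 RPKM. UHRF1, which maintains DNA methylation at replication, rose from 1.61 ± 0.125 to 8.48 ± 0.207 RPKM. Of 33 DNA replication genes, 31 were higher, 1 lower and 1 not called, with 31 and 1 adjusted over the list alone (median 1.36, camera adjusted p 9.54e-10, and adjusted p = 0.237 with an estimated correlation). The lower gene, named after its values were seen, was CCNE1, a cyclin of the G1/S transition, which fell from 278 ± 13.4 to 106 ± 41.1 RPKM. E2F8 (0.22) was not called. AURKA, a spindle kinase, rose from 8.04 ± 0.496 to 26.9 ± 0.733 RPKM, and CDK1, the mitotic kinase, from 5.14 ± 0.290 to 18.7 ± 0.947 RPKM. Of 40 mitosis genes, 39 were higher, 0 lower and 1 not called, with 39 higher adjusted over the list alone (median 1.63, camera adjusted p 1.12e-13, and adjusted p = 0.245 with an estimated correlation). The gene not called was CCNB1, at 77.7 ± 2.19 against 100.1 ± 22.2 RPKM, and it was called higher without CHIR99021 replicate 1.

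**Figure D3:**
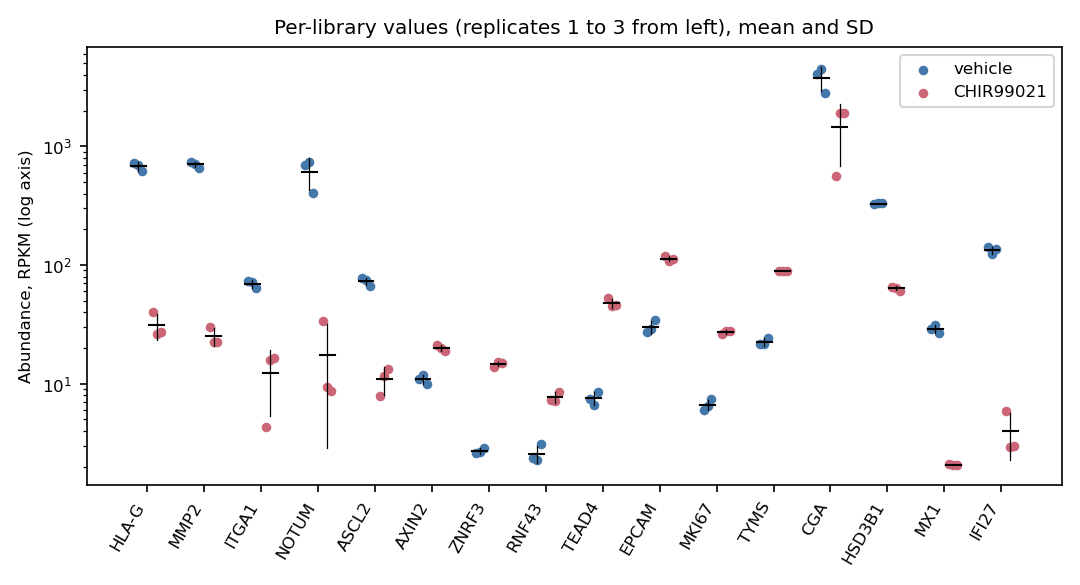
RPKM per library on a log axis for 16 genes, with the mean and SD of each group of 3. HLA-G, MMP2, ITGA1, NOTUM, ASCL2, CGA, HSD3B1, MX1 and IFI27 lie lower with CHIR99021, and AXIN2, ZNRF3, RNF43, TEAD4, EPCAM, MKI67 and TYMS higher.

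Interferon response genes fell without exception among 25 tested members, of which 25 were lower both over all genes and adjusted over the list alone. This was the only list that camera also called with an estimated correlation (adjusted p 7.44e-18 preset, and adjusted p = 0.0355 with an estimated correlation; median log2 fold change -1.42). MX1, an antiviral GTPase, fell from 29.0 ± 2.40 to 2.08 ± 0.0288 RPKM. Chosen after their values were seen were the ubiquitin-like ISG15, which fell from 195 ± 6.88 to 44 ± 19.1 RPKM, and the transcription factor STAT1, which fell from 82.5 ± 4.92 to 26.0 ± 2.71 RPKM.

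Markers of other lineages were mostly low. Of 12 primitive streak genes only HAND1 was tested, at 0.508 ± 0.0636 against 1.02 ± 0.681 RPKM and not called. Its mean with CHIR99021 was 0.630 RPKM without CHIR99021 replicate 1, so HAND1 passed the filter only through that library. T (TBXT) and GSC were listed at 0 in all 6 libraries. Of 11 amnion markers 5 were tested, with 3 lower, 0 higher and 2 not called, and 4 lower adjusted over the list alone. Without vehicle replicate 1 the count was 1 lower, and without CHIR99021 replicate 2 it was 1 higher and 2 lower. Camera's adjusted p for amnion was 0.125, or 0.0192 without CHIR99021 replicate 1. GATA6, a transcription factor of the list, fell from 17.4 ± 1.04 to 8.27 ± 4.25 RPKM. Among 4 tested fibroblast and stroma markers 2 were higher and 2 lower, with 2 and 2 adjusted over the list alone (camera adjusted p 0.570). FBN1, a microfibril protein, fell from 57.8 ± 3.29 to 21.2 ± 7.41 RPKM. The higher members, COL1A1 and TWIST1, lost their call under TPM, under median-of-ratios scaling and without vehicle replicate 2. COL1A1 also lost it without CHIR99021 replicate 2, and TWIST1 without vehicle replicate 1, vehicle replicate 3 or CHIR99021 replicate 3. COL1A2, the other lower member, kept its call only when CHIR99021 replicate 1 was the library left out, with a log2 fold change of -1.16 and of -1.61 without that library. All 5 tested endothelial and blood markers were lower, over all genes and adjusted over the list alone, with 0 higher and 0 not called (median -1.61, camera adjusted p 0.000649, and adjusted p = 0.125 with an estimated correlation). PECAM1, an adhesion molecule, fell from 4.77 ± 1.14 to 0.201 ± 0.0718 RPKM.

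Metabolic and stress lists were mixed. ADM, a vasodilator peptide induced by hypoxia, fell from 64.8 ± 5.65 to 25 ± 2.08 RPKM. The glycolytic enzymes LDHA and ENO1, chosen after their values were seen, rose from 182 ± 6.53 to 344 ± 44.8 RPKM and from 445 ± 18.5 to 777 ± 20.8 RPKM. The hypoxia and glycolysis list had 9 higher, 9 lower and 7 not called members among 25 tested, with 9 and 9 adjusted over the list alone. Its median was 0.07 (-0.053 without CHIR99021 replicate 1) and its mean -0.06, and camera pointed down with an adjusted p of 0.386. CALR, a chaperone of the endoplasmic reticulum, fell from 1002 ± 7.56 to 614 ± 30.4 RPKM. The unfolded protein and ATF4 list had 7 higher, 9 lower and 8 not called members among 24, with 7 and 9 adjusted over the list alone (median -0.07, camera adjusted p 0.125, fry adjusted p 0.0329 pointing down). Under median-of-ratios scaling 5 of its members were higher and 12 lower, with a median of -0.26. AXL, a receptor kinase and YAP/TEAD target, fell from 3.12 ± 0.999 to 0.738 ± 0.155 RPKM. YAP/TEAD targets had 3 higher, 8 lower and 5 not called members among 16 tested, with 3 and 8 adjusted over the list alone. Camera's adjusted p was 0.0380 for this list, but 0.0670 without CHIR99021 replicate 2, 0.0775 without CHIR99021 replicate 3 and 0.0742 under TPM, with an adjusted p = 0.406 with an estimated correlation.

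DHCR24, the last enzyme of cholesterol synthesis by one route, rose from 29.3 ± 1.62 to 47.3 ± 0.940 RPKM. The cholesterol list had 9 higher, 3 lower and 11 not called members among 23 tested, with 9 and 3 adjusted over the list alone (median 0.14, camera adjusted p 0.859). Counts were 15 and 4 (median 0.30) without CHIR99021 replicate 1 and 6 and 5 under median-of-ratios scaling. MT-CO3, a subunit of cytochrome oxidase, rose from 6077 ± 328 to 11463 ± 322 RPKM. Of 13 mitochondrial transcripts, 12 were higher, 0 lower and 1 (MT-ND6, called higher without CHIR99021 replicate 1) not called, with 13 higher adjusted over the list alone and 9 higher under TPM and under median-of-ratios scaling. Their median log2 fold change was 0.48 against 0.18 for all genes (camera adjusted p 0.00322, and adjusted p = 0.406 with an estimated correlation). Their share of all RPKM was 14.7% ± 0.557 with vehicle and 18.8% ± 0.193 with CHIR99021 (SD, n = 3 each).

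**Figure D4:**
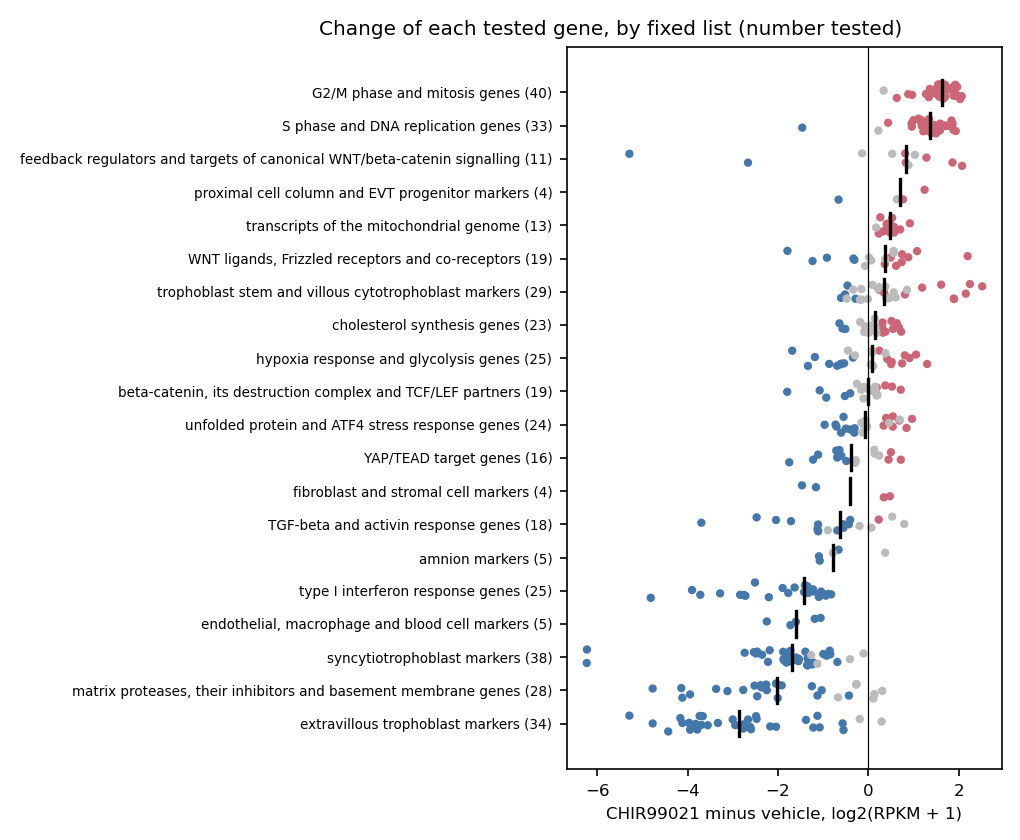
Log2 fold change (CHIR99021 over vehicle) of each tested member of the gene lists, with called genes in red (higher) or blue (lower), others in grey, and a black bar at each list's median. The medians run from -2.86 for EVT markers to 1.63 for mitosis genes.

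Of the 20 lists tested, camera called 10 at the preset correlation and 1 with an estimated correlation. With 3 libraries per group and changes in most genes, camera's comparison of a list with all other genes had little unchanged background. That background was the same at both correlations, and the cause of the difference in calls was not tested. For the TGF-beta response list the estimated correlation was -0.036, below the preset 0.01. Its adjusted p still rose from 3.4e-05 to 0.0603, so a higher correlation does not account for its lost call. The other lists that lost a call had estimates above the preset, from 0.075 to 0.44.

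The submitters' own table, from an EDGE test on transcripts, called 1582 transcripts at a corrected p under 0.05, of which 596 were higher and 986 lower with CHIR99021. They belonged to 1139 genes, and 1117 of these were also called by limma on gene sums, 1114 in the same direction. On the 31805 transcripts with at least 1 RPKM, limma called 10538, including 1568 of the 1582. Pearson r of the log2 folds from both sources was 0.955 across these transcripts, which are not independent replicates. Over 3089 transcripts above 20 RPKM, the submitters' log2 folds differed from log2 ratios of mean RPKM by a median of -0.14. The median difference was -0.006 after RPKM were scaled to equal library sums, which was not done for limma here. Counts of higher and lower calls from the 2 sources therefore rest on different scalings. In that table the signed fold of called transcripts was 23 for SLC27A2 and 5.86 for TEAD4, and -50.5 to -29.4 for MMP2.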

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

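Tests chosen only after the data were seen were those under TPM, under median-of-ratios scaling, without mitochondrial transcripts, without vehicle replicate 3 and CHIR99021 replicate 1 together, and on transcripts in place of genes.

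The count of 7477 called genes lay between 5800 and 9095 under the other filters, pseudocount, scalings and sets of libraries, and all calls shared with it had the same sign. Leaving out 1 library gave 6039 (without vehicle replicate 1) to 8875 (without CHIR99021 replicate 1). A fold minimum of 2 left 1488 genes, 707 higher and 781 lower, by its own construction. With the replicate number as a block 6803 genes were called, 6717 of them shared, and no list call changed. Deviations of equally numbered libraries from their group means correlated at -0.124, 0.146 and -0.188, so the block was not adopted.

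Among results for single genes, 588 kept direction and side of the threshold, 6 lost a call, 2 gained one and 2 turned direction. The last were CTNNB1 under TPM (-0.053) and under median-of-ratios scaling (-0.12), against 0.08 as reported; the median-of-ratios shift of all genes, -0.17, exceeds that change. CTNNB1 gained a call without CHIR99021 replicate 1. CGA and SOX15 lost theirs without vehicle replicate 1, without vehicle replicate 2, and with no filter (adjusted p 0.0680 and 0.0542); the cause was not tested.

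Among list results, 290 were kept, 16 lost a call, 7 gained one and 5 turned direction. An estimated correlation left 1 called list, with adjusted p of 0.0727 for EVT markers, 0.0905 for syncytiotrophoblast markers, 0.237 for DNA replication and 0.245 for mitosis; the cause was not tested. Fry, which does not compare a list with other genes, called WNT targets (0.00157), WNT ligands and receptors (0.00244) and stem and cytotrophoblast markers (0.00101) up, and the destruction complex (0.00441) and the unfolded protein and ATF4 list (0.0329) down. Directions turned only in lists that were not called: WNT ligands and receptors with no filter (0.874), hypoxia and glycolysis with fry (0.934), and cholesterol synthesis under median-of-ratios scaling (0.868) and without CHIR99021 replicate 2 or 3. Leaving out 1 library gave adjusted p of 0.178 to 0.912 for cholesterol; the cause was not tested. YAP/TEAD targets lost their call in 8 settings, with the highest adjusted p, 0.495, under the stricter filter, and the cause was not tested.

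Count-based fits and unique reads were not run. At 18.3 to 30.5 reads per RPKM on 1 kb, genes under 1 RPKM rest on few reads.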

Other observations

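Tests chosen only after the results were seen were those of the gene families, of sequencing depth, of RNA lost from damaged cells, of a respiratory chain pool, of RPKM taken as counts, and of transcripts in place of genes. Families were defined by symbol patterns, and their members are named after their values were seen. Translation and respiration genes rose broadly. Of 81 cytosolic ribosomal protein genes 78 were higher and 0 lower, also under median-of-ratios scaling, with a median log2 fold change of 0.85 against 0.18 for all genes. RPL14, a protein of the large subunit, rose from 297 ± 14.5 to 648 ± 9.11 RPKM (SD, n = 3). Mitochondrial ribosomal proteins were higher in 71 of 77 genes, and in 65 with 1 lower under median-of-ratios scaling. Nuclear-encoded respiratory chain genes were higher in 69 of 78, with COX6C lower, and in 53 with 2 lower under that scaling. Camera's adjusted p over 25 families was 2.53e-17, 4.42e-11 and 1.37e-08 for these families, but 0.299, 0.288 and 0.380 with an estimated correlation.

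Of 10 HLA genes 9 were lower, and HLA-A was not called (camera adjusted p 3.99e-06, but 0.213 with an estimated correlation). HLA-E, a ligand of natural killer cell receptors, fell from 112 ± 6.48 to 39.7 ± 2.60 RPKM, and HLA-C from 348 ± 9.04 to 198 ± 3.56 RPKM. Of 12 serpins 10 were lower, with SERPINF1 the only one higher, a call lost under median-of-ratios scaling. Serpins had a camera adjusted p of 1.33e-06 and the lowest of the families with an estimated correlation, at 0.136. Interleukins and their receptors had 4 higher, 11 lower and 12 not called among 27 (camera pointing down with adjusted p 0.00192, but 0.156 with an estimated correlation). Of 11 Notch pathway genes 6 were lower and 3 higher (7 and 3 under median-of-ratios scaling), and NOTCH2 fell from 43.5 ± 3.07 to 5.39 ± 1.27 RPKM while NOTCH1 rose. Proteasome subunits were higher in 26 of 40, or in 15 under median-of-ratios scaling, whereas PSMB8 and PSMB9, interferon-inducible subunits, were lower.

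CHIR99021 replicate 1 stood apart from replicates 2 and 3. It differed by at least 2-fold from both in 377 genes, 220 higher and 157 lower, where each other library did so in 2 to 7 genes. TUBB2B, a neuronal tubulin, was at 104 RPKM there against 8.87 and 9.01, and LEP, the leptin gene, at 14.0 against 68.6 and 69.8 RPKM. RNA of vehicle-treated cells in that library would place most of these genes between the groups, but 65 of 377 (17.2%) lay there, and lower depth is opposed by its total of 29599909 reads (29.6 in units of 1e6), between those of the other libraries of its group. A difference between the cultures, or in handling, could remain and was not tested, since the labels give neither.

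Mitochondrial transcripts took a larger share of RPKM with CHIR99021. Scaling by total reads as the whole cause is opposed by the 9 of 13 transcripts still called higher under median-of-ratios scaling. Loss of nuclear-encoded mRNA from damaged cells would by itself raise all 13 by 1 factor. The highest and lowest log2 fold changes, of MT-CO3 and MT-ND6, lay 0.75 apart. The standard error of 0.10 for that difference does not allow for picking the extremes or for shared libraries. Such a loss with changes of single transcripts on top cannot be excluded in this way. A first choice of test for this loss, the nuclear-encoded respiratory chain genes, was dropped because their rise does not bear on it. A larger pool of respiratory chain RNA from both genomes with CHIR99021 may contribute, and stays open. Of 78 nuclear-encoded genes 69 were higher. Camera gave them an adjusted p of 1.37e-08 at the preset correlation and 0.380 with an estimated correlation. The latter cannot decide the question, because no family was called in that test, where the lowest adjusted p was 0.136.

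The submitters' table called few transcripts for the changes it holds. Testing transcripts in place of genes is opposed by the 10538 transcripts that limma called, and adjustment over transcripts near 0 by the 2184 calls their p-values gave over the 31805 transcripts with at least 1 RPKM. A candidate explanation is that the test took RPKM as if they were read counts. For 93.6% of 18789 low transcripts, with summed RPKM of 6 to 30, a binomial test on rounded RPKM gave their p within 10%. Of transcripts with at least a 4-fold change, that table called 112 of 112 with a mean of at least 20 RPKM but 94 of 1157 (8.12%) under 5 RPKM. This contrast cannot decide the question, because a test on read counts would also call fewer changes at low abundance.

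Of the 10 splits of the 6 libraries into groups of 3, only 1, the real one, gave as many as 7477 genes, and the highest other gave 0 in limma. At an unadjusted p under 0.05 the others gave 13 to 239 genes, against 8062. These 10 splits are too few for a share under 0.05. Each other split also put libraries of both treatments in each group, which adds the treatment difference to the spread within groups. Few calls were therefore bound to follow, and the splits cannot show what unrelated libraries would give.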
